A study of Solanum tuberosum with 9 samples.

How the data were processed

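RNA was sequenced from stolons of the potato variety Kexin 13, the underground shoots whose tips swell into tubers. The plants received 3 nitrogen treatments, named in the labels as deficiency (AN0), conventional supply (AN1) and excess (AN2). Each treatment has 3 libraries, numbered 1 to 3. Total RNA was extracted with TRIzol and libraries were made with the VAHTS Universal V6 kit, per the labels' protocols. Nothing in the labels says whether the 3 libraries of a treatment came from separate plants, pots or plots. The p-values therefore measure only the spread between these libraries, which may be technical in part.

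The deposited count table holds whole-number read counts per gene for 25702 genes, with no normalization, and 1 column per library. The authors' FPKM table covers the same genes in FPKM, fragments per gene scaled for gene length and library total. The deposited FPKM values equal count divided by gene length and by the library's summed counts, with a largest relative difference of 1.71e-07 after gene lengths were rounded to whole bases, so both tables carry the same measurements. The submitters' processing notes name fastp, HISAT2, HTSeq, R 3.2.0 and DESeq2, without roles or settings. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. No gene coordinates are printed for that reason. Library totals ran from 30952622 to 38235348 counts.

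Gene names came from a RefSeq gene table of the assembly SolTub_3.0. Of the 25702 gene IDs, 25672 matched a symbol there. A symbol that is more than a locus number was found for 214 genes, and 263 further genes have a locus number with a synonym, which gives 477 named genes, of which 451 were tested. The remaining genes, known by number only, hold 88.3% of all counts. No product names were used here. Statements on gene groups therefore cover a small, well-studied part of the genes. Synonyms that several genes share, such as LOX1 or the patatin names, mark families whose members have similar sequences. How the counting split reads among such copies is not known, so their single values are uncertain.

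The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, on counts with TMM factors. Genes were kept by filterByExpr, which left 21223. All 9 libraries entered 1 model with a mean per treatment, robust dispersions and no covariate. Calls are Benjamini-Hochberg adjusted p-values under 0.05, with no minimum fold change. The 3 pairwise comparisons and a 3-group F-test were run. Values per gene are TMM-scaled CPM (counts per library scaled to a fixed total), given as mean ± SD over 3 libraries, and log2 fold changes are given with their standard error. The standard error was taken from the fold change and the F statistic. The common biological coefficient of variation was 0.417.

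The gene lists planned before the data were examined were 32 name patterns, written for product names. Applied to symbols and synonyms alone, they filled 1 list to the required 5 tested members. For that reason 25 lists with 271 members were filled by hand from the symbols and synonyms. This was done before any comparison was run, but after the 40 most abundant genes had been looked at. The lists are starch synthesis, starch breakdown, sucrose metabolism and transport, tuber storage proteins and protease inhibitors, nitrogen uptake and assimilation, amino acid and polyamine synthesis, regulators of tuberization, flowering and meristems, abscisic acid, ethylene, lipoxygenase and jasmonate, pathogenesis-related and defence proteins, WRKY factors, burst oxidases with calcium-dependent and MAP kinases, glycoalkaloids and sterols, phenylpropanoids and flavonoids, photosynthesis as a marker of green tissue, mitochondrial respiration, cold, drought and heat, ribosomal proteins, cell wall, ascorbate and glutathione, ion channels and pumps, 14-3-3 proteins, cytokinin oxidases, and D-type cyclins. The 21 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM (prior count 2), with a preset inter-gene correlation of 0.01 and adjustment over the lists of a comparison. Camera was repeated with an estimated correlation, a version that also tests on the 6 residual degrees of freedom of the fit. Fry tested whether a list's members moved, on balance, in 1 direction. A list score per library is the mean over its genes of log2 CPM minus the gene's mean over the 9 libraries.

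The genes named in the text follow a rule fixed before the data were examined. Per comparison it takes the 4 named genes with the largest rise and the 4 with the largest fall among called genes with a mean of at least 5 CPM and no overlap between the groups. It adds the 2 called members with the smallest adjusted p of each of the first 8 lists by camera p, and anchor genes given whether called or not. The anchors found by symbol were nitrate reductase, nitrite reductase, glutamine synthetase, patatin, granule-bound starch synthase, sucrose synthase and FT. Genes given outside this rule, as further examples of a list or as other named calls, were chosen after their values were seen. Their alternatives were computed in the same way. A gene that the rule takes is not reported here.

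The overlap of calls between comparisons that share libraries was set beside 20 simulations of unchanged groups. The procedure was tested on simulated data, counts in which 200 genes were changed by known folds. For AN0 against AN1 the test recovered 40.3% of the genes changed 4-fold and 77.3% of those changed 8-fold among 21223 genes, but 2.99% of those changed 2-fold. The corresponding shares were 50.7%, 84.8% and 2.99% for AN2 against AN1, and 49.3%, 87.9% and 5.97% for AN2 against AN0. Wrong calls numbered 1 of 81, 8 of 100 and 10 of 105. The simulated counts gave each gene 1 spread for all groups and held no outlying library. In the data the spread differed between groups, so these rates may not hold there.

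Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE and upper-quartile factors, no filter on low counts, at least 10 counts in 6 libraries, a replicate block, limma-trend on log2(FPKM+1) and log2(FPKM+0.1), a fit to only the 2 groups compared, a 2-fold minimum, no robust dispersion, and leaving out each library. Chosen after seeing the data were leaving out AN0-1 and AN2-3 together, voom with sample quality weights, a gene length correction per library, and lists by name pattern only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.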

Results

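Transcripts were counted in 9 libraries from stolons of the potato variety Kexin 13, with 3 libraries each from plants under nitrogen deficiency (AN0), conventional nitrogen (AN1) and excess nitrogen (AN2). The series asks how tuber formation responds to nitrogen supply. The total counts were 35561445, 37724251 and 36592484 in AN0-1 to AN0-3, 32143659, 32136111 and 38235348 in AN1-1 to AN1-3, and 34739034, 35021190 and 30952622 in AN2-1 to AN2-3. Between 22832 and 23745 genes had at least 1 count per library. Libraries of a group correlated with r between 0.885 and 0.974 across genes on the log2 CPM scale (genes are not independent replicates). No pair of libraries agreed within sampling noise.

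The stolon libraries were rich in tuber storage transcripts, but unevenly so. Patatin, the main storage protein of the tuber (LOC102605260), took between 1.06% and 1.80% of the counts in 7 libraries, 0.357% in AN0-1 and 0.0485% in AN2-3. The score of the 6 genes for storage proteins and protease inhibitors was -1.36 in AN0-1 and -3.89 in AN2-3, and between -0.83 and 1.27 in the other 7. The same 2 libraries had the highest photosynthesis scores, 5.45 in AN0-1 and 4.17 in AN2-3, against -3.44 to 0.88 elsewhere. PSBR, a subunit of photosystem II and the most abundant of the photosynthesis genes tested, stood at 279 CPM in AN0-1 and 299 CPM in AN2-3, against 9.52 to 80.4 CPM elsewhere. The gene cab1 (LOC102596966), for a chlorophyll-binding protein, stood at 243 CPM in AN0-1, 5.63 CPM in AN2-3 and no more than 2.44 CPM in the others. With all 9 libraries the storage list was not called in any comparison. It gave camera adjusted p = 0.497 for AN0 against AN1, 0.114 for AN2 against AN1 and 0.460 for AN2 against AN0, and 0 of its 6 genes were called in any of them by edgeR or DESeq2, or had an unadjusted p under 0.05. Without AN2-2, though, camera called the storage list lower in AN2 than in AN1 (camera adjusted p = 0.00855) and than in AN0 (0.0432), while over the other alternatives for these comparisons its adjusted p reached 0.459 and 0.911. With all 9 libraries the 4 tested photosynthesis genes were too few for camera. Their median log2 fold change was 4.04 for AN0 and 3.32 for AN2, both against AN1, with 0 called by edgeR or DESeq2 and 2 and 1 at an unadjusted p under 0.05. Camera tested the photosynthesis list in the 7 fits without 1 library other than AN0-1 or AN2-3, where more of its genes passed the filter, and called it higher in AN0 than in AN1 without AN0-3 (camera adjusted p = 0.00313), AN1-3 (0.0183) or AN2-1 (0.0431), but not in the other 4 (up to 0.135). In those 7 fits the photosynthesis list was not called for AN2 against AN1 (camera adjusted p from 0.0811 to 0.359) or AN2 against AN0 (from 0.273 to 0.934).

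**Figure D1:**
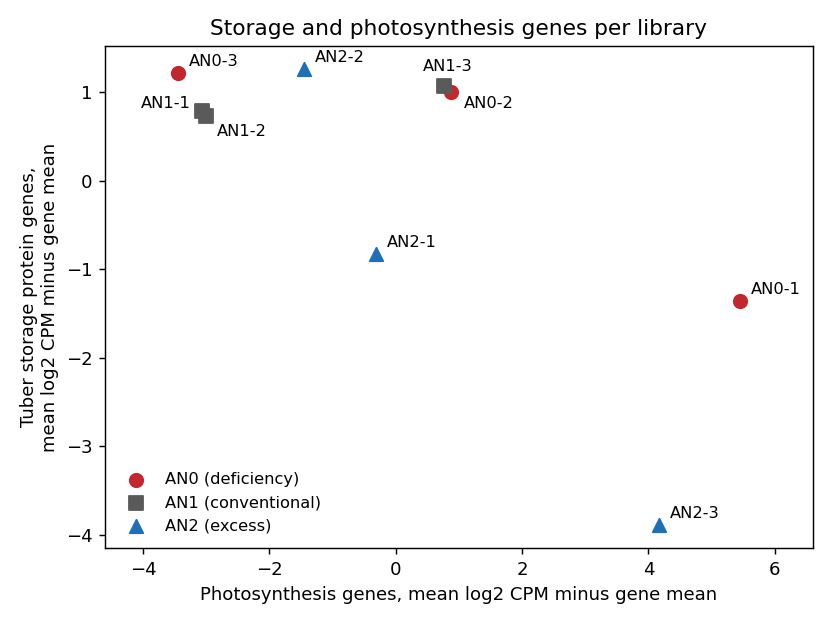
Each point is 1 stolon library, with the mean log2 CPM of 4 photosynthesis genes on the horizontal axis and that of 6 tuber storage protein genes on the vertical axis, both relative to each gene's mean over the 9 libraries. AN0-1 (5.45, -1.36) and AN2-3 (4.17, -3.89) lie apart from the other 7 libraries.

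Nitrogen deficiency against conventional supply addressed the response of stolons to a shortage. Of the named genes edgeR called only VPE2, which encodes a vacuolar processing enzyme (a cysteine protease of the vacuole). It rose from 15.5 ± 1.98 CPM in AN1 to 69.3 ± 14.4 CPM in AN0 (SD, n = 3), a log2 fold change of 2.16 ± 0.24 (SE, edgeR adjusted p = 0.0418). The 2 enzymes that reduce nitrate to ammonium had higher means under deficiency without passing the test. Nitrate reductase NR3 stood at 19.6 ± 6.15 CPM in AN0 and 2.34 ± 0.67 CPM in AN1 (log2 fold change 3.07 ± 0.57), and nitrite reductase NIR at 8.01 ± 4.86 and 0.65 ± 0.43 CPM (3.63 ± 0.70), both with edgeR adjusted p = 0.134. All AN0 libraries lay above all AN1 libraries for both genes. NR3 was called in 4 of 21 alternatives, 1 of them the fit without AN2-3, and NIR in 3, 1 of them without AN0-3 (edgeR and other tools' adjusted p from 1.27e-05 to 0.498 for NR3 and from 1.02e-05 to 0.490 for NIR).

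Camera called the nitrogen uptake and assimilation list higher in AN0. All 8 of its genes had positive log2 fold changes against AN1, with a median of 1.10. Over all genes edgeR called 0 of the 8 and DESeq2 3 higher, 5 had an unadjusted p under 0.05, and 5 rose when adjusted over the list alone. The camera adjusted p was 2.37e-06 with the preset correlation, and the adjusted p = 0.0920 with an estimated correlation. Besides NR3 and NIR the list holds the amino acid permease aap1 (LOC102597666, 1.17 ± 0.28, edgeR adjusted p = 0.194) and a glutamine synthetase (LOC102596783, 0.41 ± 0.24, edgeR adjusted p = 0.593). The lipoxygenase and jasmonate list had 9 of 9 genes positive and a median of 1.503. In it edgeR called 0 genes over all genes and DESeq2 3 higher, 6 had an unadjusted p under 0.05, and 3 rose when adjusted over the list alone (camera adjusted p = 1.86e-05, adjusted p = 0.0532 with an estimated correlation). Its members include HPL, a hydroperoxide lyase, at 25.0 ± 2.26 CPM in AN0 and 8.82 ± 1.28 CPM in AN1 (edgeR adjusted p = 0.0530, and called without AN0-3 or AN2-3, with a range of 2.32e-09 to 0.305 over the alternatives). Another is LOC102602192, a lipoxygenase that shares its synonym lox with another gene and whose values are uncertain for that reason (2.13 ± 0.58, edgeR adjusted p = 0.233). The nitrogen score was 1.30 in AN0-1, the library with the highest photosynthesis score, and 0.63 and 0.72 in the other AN0 libraries. Camera also called both lists with each library left out in turn, with an adjusted p of at most 0.0002 for nitrogen and 0.00156 for lipoxygenases.

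The other 5 lists called in this comparison had medians of at most 0.66 in size, and their calls depended on single libraries. Sucrose metabolism and transport had 13 of 13 genes positive (median 0.34, camera adjusted p = 0.0289, and adjusted p = 0.252 with an estimated correlation), but its call ended without AN0-2, AN0-3, AN1-1 or AN1-2 (adjusted p of up to 0.113). Abscisic acid had 9 of 11 positive (median 0.53, camera adjusted p = 0.0289, and adjusted p = 0.189 with an estimated correlation). That call ended without AN0-3, AN1-1 or AN1-2 (up to 0.176). Pathogenesis-related and defence proteins had 9 of 11 positive (median 0.38, camera adjusted p = 0.0289, and adjusted p = 0.252 with an estimated correlation), and the call ended without AN0-3 (0.176). Phenylpropanoids and flavonoids had 9 of 11 positive (median 0.66, camera adjusted p = 0.0490, and adjusted p = 0.493 with an estimated correlation), with the call lost without any 1 of the AN0 libraries, AN1-1 or AN1-2 (up to 0.200), and without AN0-1 and AN2-3 together. There the flavonol synthase FLS reached 97.6 CPM in AN0-2 and 2.41 CPM or less in the other AN0 libraries. Glycoalkaloids and sterols stood lower, with 3 of 8 positive and a median of -0.66 (camera adjusted p = 0.0490, and adjusted p = 0.571 with an estimated correlation). This call was lost without AN0-1, AN0-3, AN1-1, AN1-2 or AN2-3, with the replicate block, and without AN0-1 and AN2-3 together (up to 0.176). In none of these 5 lists was a gene called over all genes by edgeR, while DESeq2 called 2 defence genes and 1 abscisic acid gene higher and 1 glycoalkaloid gene lower. Adjusted over the list alone, 2 defence genes were higher and 1 glycoalkaloid gene lower.

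In all, edgeR called 8 genes higher and 2 lower in AN0 than in AN1 among 21223, with 2301 at an unadjusted p under the same threshold. DESeq2 called 460 higher and 196 lower, and the voom fit with quality weights 689 and 338. The count of 10 became 0 without AN0-1, AN0-2, AN1-1, AN1-2, AN1-3 or AN2-1, 5 without AN2-2, 35 without AN2-3 and 109 without AN0-3, and 0 without AN0-1 and AN2-3 together. VPE2 lost its call in 10 of 21 alternatives, among them the fits without AN0-1, AN0-2, any 1 of the AN1 libraries or AN2-1. Its adjusted p ranged from 8.90e-13 to 0.289 over edgeR and the other tools, while its log2 fold change stayed between 2.00 and 2.32. The other anchor genes were not called by edgeR, with log2 fold changes of 1.01 ± 0.72 for GBSS (edgeR adjusted p = 0.688), 0.34 ± 0.57 for sucrose synthase SS16 (0.910), 1.47 ± 0.67 for FT (0.474) and -0.44 ± 1.03 for patatin (LOC102605260, 0.941). Limma-trend on log2(FPKM+1) gave 18 higher and 7 lower, and on log2(FPKM+0.1) 2 higher and 1 lower.

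**Figure D2:**
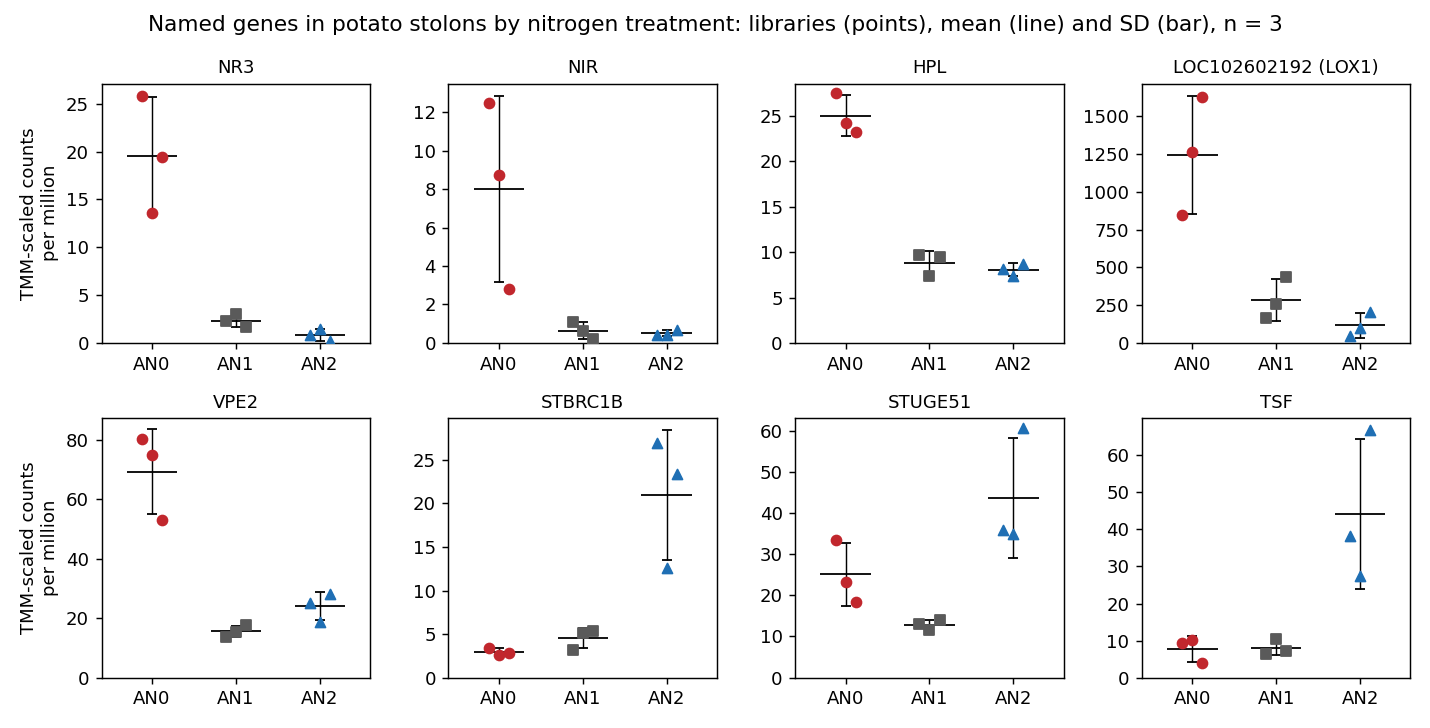
TMM-scaled CPM of 8 genes in each library (points), with the mean (line) and SD (bar) of 3 libraries per treatment. The means of NR3, NIR, HPL, LOC102602192 and VPE2 are highest in AN0, with NR3 at 19.6 (AN0), 2.34 (AN1) and 0.84 CPM (AN2), and those of STBRC1B, STUGE51 and TSF in AN2.

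Nitrogen excess against conventional supply gave mostly rises. STBRC1B, a BRANCHED1 transcription factor that restrains the growth of axillary buds, rose from 4.57 ± 1.18 to 20.97 ± 7.51 CPM (SD, n = 3; log2 fold change 2.20 ± 0.34, edgeR adjusted p = 0.0372). TSF rose from 8.05 ± 2.04 to 44.1 ± 20.3 CPM (2.45 ± 0.44, edgeR adjusted p = 0.0492). STUGE51, a UDP-glucose epimerase of cell wall sugar supply, rose from 12.9 ± 1.21 to 43.7 ± 14.6 CPM (1.76 ± 0.30, edgeR adjusted p = 0.0428). Other named calls were PLC1 (1.70 ± 0.31, edgeR adjusted p = 0.0492) and pp34 (LOC102577743, 1.66 ± 0.29, 0.0447), both higher.

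Starch synthesis genes had lower values under excess. In that list 8 of 9 genes had negative log2 fold changes with a median of -0.83, with 0 called by edgeR over all genes or over the list alone, 0 by DESeq2 and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.0358, and adjusted p = 0.686 with an estimated correlation). Granule-bound starch synthase GBSS, the amylose-forming enzyme, had a log2 fold change of -0.98 ± 0.72 (edgeR adjusted p = 0.641). It stood at 187 CPM in AN2-3, against 1957 and 2020.1 CPM in the other AN2 libraries. The list's call ended without AN2-3, the library with the lowest storage score (-3.89), and without AN1-1, AN1-2 or AN1-3 (adjusted p of up to 0.0827). Starch breakdown had 5 of 5 negative (median -0.65, camera adjusted p = 0.0495, and adjusted p = 0.390 with an estimated correlation). Amino acid and polyamine synthesis had 12 of 18 negative (median -0.16, camera adjusted p = 0.0495, and adjusted p = 0.473 with an estimated correlation). Both of these calls were lost without AN0-1, AN1-1, AN1-2, AN1-3 or AN2-2 and with the replicate block. Starch breakdown lost its call also without AN2-3 and without AN0-1 and AN2-3 together, and amino acids without AN2-1 (adjusted p of up to 0.182 and 0.136). In these 2 lists edgeR called 0 genes over all genes or over the list alone, 1 and 3 had an unadjusted p under 0.05, and DESeq2 called 0 and 2.

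Regulators of tuberization, flowering and meristems stood higher in AN2, with 14 of 19 positive and a median of 0.77. By edgeR STBRC1B was the only member called over all genes, with 4 at an unadjusted p under 0.05 and 4 higher when adjusted over the list alone, and DESeq2 called 4 higher (camera adjusted p = 0.0358, and adjusted p = 0.495 with an estimated correlation). The GAI gene (LOC102587893), a repressor of gibberellin responses, had 1.32 ± 0.33 (edgeR adjusted p = 0.119), and FT had 1.40 ± 0.67 (edgeR adjusted p = 0.405). The call ended without AN1-1 or AN2-1 and with the replicate block (adjusted p of up to 0.132). For abscisic acid edgeR called 0 genes over all genes or over the list alone, and DESeq2 called 2 higher. An unadjusted p under 0.05 was found for 4. This list had 8 of 11 positive with a median of 0.50 (camera adjusted p = 0.0495, and adjusted p = 0.390 with an estimated correlation). In it nced1 (LOC102577783), for the enzyme that commits carotenoids to abscisic acid, had 1.73 ± 0.56 (edgeR adjusted p = 0.210). That call was lost without AN0-1, AN1-1, AN1-2, AN2-1 or AN2-2 and with the replicate block (up to 0.112). The nitrogen list was not called here (camera adjusted p = 0.222, 5 of 8 positive), with 0 genes called by edgeR, 2 by DESeq2 and 4 at an unadjusted p under 0.05. Nitrate reductase NR3 had a log2 fold change of -1.48 ± 0.56 (edgeR adjusted p = 0.279) and NIR -0.32 ± 0.67 (0.917). Glutamine synthetase (LOC102596783) had -0.04 ± 0.24 (edgeR adjusted p = 0.969), patatin -0.79 ± 1.04 (0.846) and sucrose synthase SS16 -1.07 ± 0.58 (0.476).

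The edgeR test called 137 genes higher and 11 lower in AN2 than in AN1, with 2930 at an unadjusted p under the threshold. DESeq2 called 930 higher and 305 lower, and the voom fit with quality weights 2976 and 2284, which lowers the share of higher calls from 92.6% to 75.3% and 56.6%. The count of 148 became 0 without AN1-1, AN1-3 or AN2-1, 1 without AN1-2 or AN2-3, 10 without AN0-2, 96 without AN0-3 and 367 without AN2-2, and 15 without AN0-1 and AN2-3 together. STBRC1B, TSF and STUGE51 were each called in 11 to 12 of 21 alternatives, all with positive log2 fold changes of at least 1.45. All 3 lost their calls without AN0-2, AN1-1, AN1-2, AN1-3, AN2-1 or AN2-3, TSF also without AN0-1, and all 3 without AN0-1 and AN2-3 together. Their adjusted p values over edgeR and the other tools reached 0.212 for STBRC1B, 0.244 for TSF and 0.222 for STUGE51, with lowest values of 6.74e-07, 7.59e-06 and 9.45e-06. PLC1 and pp34 (LOC102577743) lost theirs without the same 6 libraries or AN0-3, and PLC1 also without AN0-1 (up to 0.226 and 0.212).

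Excess against deficiency, the ends of the nitrogen range, gave the most calls. Nitrate reductase NR3 fell from 19.6 ± 6.15 CPM in AN0 to 0.84 ± 0.61 CPM in AN2 (log2 fold change -4.55 ± 0.62, edgeR adjusted p = 0.00965), and NIR from 8.01 ± 4.86 to 0.51 ± 0.16 CPM (-3.95 ± 0.71, edgeR adjusted p = 0.0244). The lipoxygenase LOC102602192 fell from 1245 ± 391 to 116 ± 83.0 CPM (-3.42 ± 0.61, edgeR adjusted p = 0.0246), and the hydroperoxide lyase HPL from 25.0 ± 2.26 to 8.05 ± 0.70 CPM (-1.64 ± 0.20, edgeR adjusted p = 0.00762). The cytosolic fructose-1,6-bisphosphatase LOC102588954, an enzyme of sucrose synthesis, fell by 2.77 ± 0.38 on the log2 scale (edgeR adjusted p = 0.00965). Starch synthase LOC102583115 (SS2) fell by 1.81 ± 0.40 on the same scale (edgeR adjusted p = 0.0427). STBRC1B rose from 2.97 ± 0.42 to 20.97 ± 7.51 CPM (log2 fold change 2.82 ± 0.35, edgeR adjusted p = 0.00762). On the log2 scale TSF rose by 2.50 ± 0.44 (edgeR adjusted p = 0.0241) and RSI5 by 2.36 ± 0.45 (0.0284).

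The lipoxygenase and jasmonate list had 8 of 9 genes negative with a median of -1.64. In it 2 genes fell over all genes by edgeR and 6 when adjusted over the list alone (camera adjusted p = 0.000849, and adjusted p = 0.111 with an estimated correlation). Starch synthesis had 8 of 9 negative with a median of -1.38, where 1 gene fell over all genes by edgeR and 5 when adjusted over the list alone (camera adjusted p = 0.00132, and adjusted p = 0.417 with an estimated correlation). Starch breakdown had 5 of 5 negative with a median of -0.87, 0 called over all genes by edgeR, 3 lower by DESeq2, 4 at an unadjusted p under 0.05 and 4 lower when adjusted over the list alone (camera adjusted p = 0.00402, and adjusted p = 0.133 with an estimated correlation). Amino acid and polyamine synthesis had 15 of 18 negative with a median of -0.41, 0 called either way by edgeR, 4 lower by DESeq2 and 6 at an unadjusted p under 0.05 (camera adjusted p = 0.0101, and adjusted p = 0.236 with an estimated correlation). Camera also called these 4 lists with each library left out in turn and without AN0-1 and AN2-3 together. In AN2-3, with its storage score of -3.89, the starch synthesis score was -1.80, against -0.27 and -0.24 in the other AN2 libraries. The nitrogen list itself missed the threshold (camera adjusted p = 0.0753), with 2 genes called lower by edgeR and by DESeq2 and 3 of 8 genes positive. It was called lower without AN0-2 (camera adjusted p = 0.0395) or AN2-3 (0.0122), and without AN0-1 and AN2-3 together (0.0360).

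The anchor genes that were not called by edgeR included GBSS (-1.99 ± 0.74, edgeR adjusted p = 0.163), SS16 (-1.41 ± 0.58, 0.214), glutamine synthetase (LOC102596783, -0.45 ± 0.24, 0.326), patatin (LOC102605260, -0.35 ± 1.03, 0.891) and FT (-0.07 ± 0.65, 0.965). Further named genes called higher in AN2 were the auxin-response repressor IAA2 (1.54), the sterol reductase StSSR1 (LOC102604696, 1.48), AP1 (1.95), pp34 (LOC102577743, 1.42), the NADH dehydrogenase NDA1 (LOC102598594, 2.25) and StPCL1 (LOC102600588, 0.99), with edgeR adjusted p from 0.00975 for IAA2 to 0.0480 for NDA1. Genes called lower included VPE2 (-1.52, edgeR adjusted p = 0.0160) and the phosphate transporter PT1 (-1.06, 0.0406). IAA2 was called in 20 of 21 alternatives and VPE2 in 17, with VPE2 lost without AN0-2 or AN2-1 (up to 0.0654). The calls of AP1, pp34, StPCL1, NDA1, StSSR1 and PT1 were kept in 9 to 12, and each of them was lost without AN0-2, AN1-1, AN1-3 or AN2-1 (adjusted p of up to 0.150). Except for StSSR1 they were also lost without AN0-1, except for PT1 without AN0-3, and except for AP1 and PT1 without AN2-3, while NDA1 and PT1 were lost without AN1-2 and PT1 without AN2-2.

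**Figure D3:**
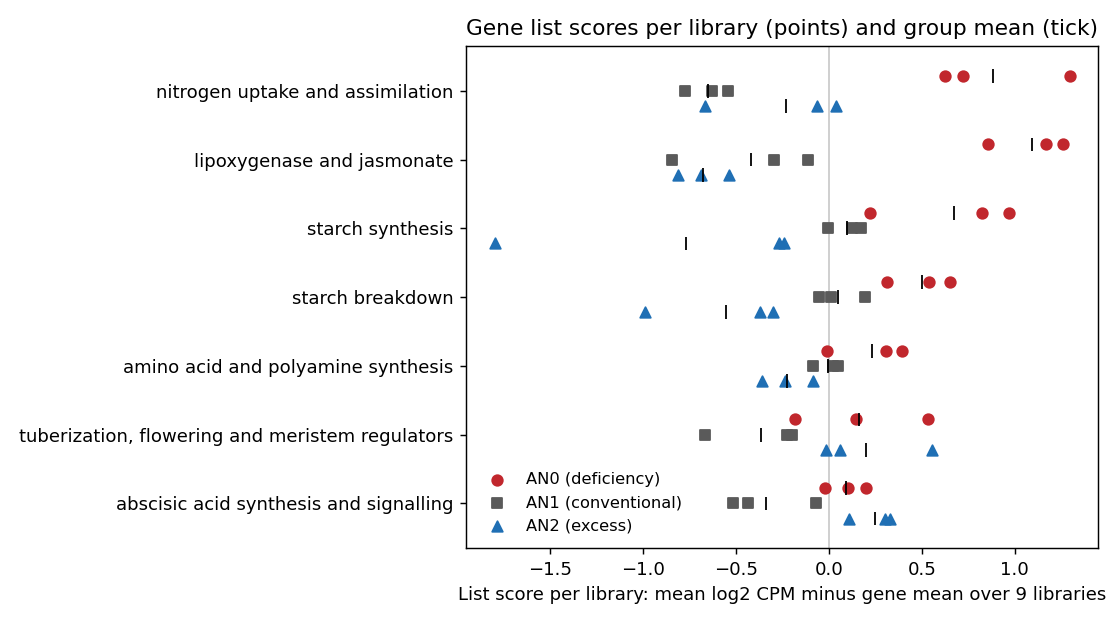
Scores of 7 gene lists in each library (points) with the group mean (tick), as mean log2 CPM relative to each gene's mean over the 9 libraries. The 3 AN0 libraries lie between 0.63 and 1.30 for nitrogen uptake and assimilation, above all others, and AN2-3 lies at -1.80 for starch synthesis.

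In all, 498 genes were called higher and 276 lower in AN2 than in AN0 by edgeR, with 4333 at an unadjusted p under the threshold. DESeq2 called 1523 higher and 1203 lower, and limma-trend on log2(FPKM+1) 870 and 247, so the share of higher calls was 55.9% and 77.9% with those tools, beside 64.3% by edgeR. It was 48.9% in the voom fit with quality weights (2878 higher, 3004 lower). The count of 774 became 378 without AN0-1, 110 without AN0-2, 350 without AN1-1, 490 without AN1-2, 276 without AN1-3, 155 without AN2-1 and 312 without AN2-3, and 296 without AN0-1 and AN2-3 together. NR3, HPL, STBRC1B and LOC102588954 were called in all 21 alternatives, LOC102602192 in 18, TSF in 15, NIR and RSI5 in 14 and LOC102583115 in 12. NIR and RSI5 lost their calls without AN0-1, AN0-2, AN2-1 or AN2-3, and RSI5 also without AN1-2. TSF lost its call without AN0-1, AN0-2 or AN2-1, and LOC102602192 without AN0-2 or AN2-1. LOC102583115 lost it without any 1 of the AN0 or AN1 libraries or AN2-1. Without those libraries or in the other alternatives, the adjusted p reached 0.0946 for NIR, 0.104 for RSI5, 0.0817 for TSF, 0.0769 for LOC102602192 and 0.134 for LOC102583115.

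Across the 3 treatments the F-test of edgeR called 595 genes, with 4058 at an unadjusted p under the threshold. It called 370 without AN0-1, 111 without AN0-2, 143 without AN1-1, 131 without AN1-2, 201 without AN1-3, 85 without AN2-1 and 253 without AN2-3, and 220 without AN0-1 and AN2-3 together. DESeq2 called 2810.

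Deficiency and excess, each against conventional supply, shared 0 called genes by edgeR, where lists drawn independently would share 0.0516 higher and 0.00104 lower genes, and the simulated unchanged groups shared 0. By DESeq2 they shared 93 in the same direction. Across genes the 2 sets of log2 fold changes correlated with r = 0.220, while simulated unchanged groups with the shared AN1 libraries gave 0.5004 (genes are not independent replicates). The covariance was 0.173 against 0.161 simulated, a difference of 0.0118. Part of any excess may come from the shared AN1 libraries, which are too few to split. The comparisons of AN2 with AN1 and with AN0, which share the AN2 libraries, had 111 calls in the same direction (104 higher, 7 lower), against 3.21 higher and 0.143 lower for independent lists and 0 in the simulation. The covariance there was 0.671 against 0.160 simulated, a difference of 0.511. Of the 10 genes called in AN0 against AN1, 9 were called in the opposite direction in AN2 against AN0, against 0.151 for independent lists. These comparisons share the AN0 libraries with opposite sign, which by itself favours opposite changes, and the covariance was -0.553 against -0.161 simulated, a difference of -0.392. The simulation gave each gene 1 spread for all groups. In the data the mean SD of log2 CPM was 0.593 in AN0, 0.550 in AN2 and 0.396 in AN1. Noise of shared AN0 or AN2 libraries could therefore enlarge a covariance beyond the simulated one. The differences from the simulation thus do not measure a shared response.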

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

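The fit without AN0-1 and AN2-3, the voom fit with quality weights, the gene length correction and the lists by name pattern were chosen after the data were seen. Counts of calls depended on the tool and on single libraries. For named genes, 49 fold changes were followed over 1029 alternative fits of them. Of these, 836 kept their side of the threshold, 168 lost their call, 25 gained one and 0 called values reversed. The 836 include many fits of results that were not called at first and stayed so, while all 168 losses fell on called results. The called results were therefore less stable than these pooled numbers make them look. Called genes were chosen on the same libraries that the alternatives reuse, so a reversal was unlikely from the start. Some values that were not called changed sign, such as FT in AN2 against AN0 (log2 fold change from -0.75 to 0.88). The causes of the shifts below were not tested except where stated. Filters, RLE and upper-quartile factors, the 2-fold minimum and non-robust dispersions kept each count of called genes within 1.5 times.

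For AN0 against AN1 (10 genes), DESeq2 called 656, log2(FPKM+1) 25, log2(FPKM+0.1) 3, quality weights 1027, the gene length correction 16, and both the 2-group fit and the fit without AN0-1 and AN2-3 called 0. For AN2 against AN1 (148), DESeq2 called 1235, log2(FPKM+1) 384, log2(FPKM+0.1) 280, quality weights 5260, the 2-group fit 45 and the fit without AN0-1 and AN2-3 15. For AN2 against AN0 (774), DESeq2 called 2726, quality weights 5882, the gene length correction 1504, the 2-group fit 119 and the fit without AN0-1 and AN2-3 296. For all 3 treatments (595), DESeq2 called 2810, quality weights 7799 and the fit without AN0-1 and AN2-3 220. The quality weights ran from 0.293 (AN0-1) to 5.33 (AN2-1), so that fit gives most weight to few libraries. The 2-group fits have fewer samples to estimate the spread.

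Leaving out 1 library at a time gave 0 to 109, 0 to 367 and 110 to 1077 calls for the 3 comparisons in that order, and 85 to 793 for all treatments. Lists called ranged from 3 to 10, 0 to 5 and 4 to 9. The overlap of the first 2 comparisons was 0 to 2 genes, and 93 with DESeq2.

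Calls of lists depended on the version of the list test. With an estimated correlation 0 lists were called in each comparison, where the preset value gave 7, 5 and 4. A higher correlation does not explain every loss. The estimate lay below the preset 0.01 for lipoxygenases (-0.0082), starch breakdown (-0.036) and abscisic acid (8.0e-05), whose calls were lost too. That version of camera also tests on the 6 residual degrees of freedom of the fit, which the preset version does not. This raises p-values whatever the correlation, and its share in the losses was not examined. Fry called 2 lists for AN0 against AN1, nitrogen (fry adjusted p = 0.0113) and lipoxygenases (0.00395), and 0 for AN2 against AN1. For AN2 against AN0 it called 3, lipoxygenases (fry adjusted p = 0.00182), starch breakdown (0.00581) and amino acids (0.0190). Starch synthesis was not called by fry there (0.0574). Without AN0-1 and AN2-3, 8 lists were called for AN2 against AN0. Lists by name pattern gave 0 calls in each comparison, since 1 list had enough members.

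Replicate numbers are shared between the groups, but nothing in the labels ties them. Of 9 same-numbered pairs 0 had deviations that correlated above 0.1 (range -0.47 to 0.08), and 2 of 9 libraries matched their own number best. With the replicate block 0, 5 and 166 genes were called in the 3 comparisons, 101 for all treatments, and 1 list for AN2 against AN1. Library totals ran from 30952622 to 38235348 counts, and whether more depth would add calls was not tested. The spread between libraries was larger in AN0 and AN2 (mean SD of log2 CPM 0.593 and 0.550) than in AN1 (0.396).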

Other observations

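The tests of depth, dilution, exchanged labels and scaling below were chosen after the result was seen. The tests of green tissue for the reductases, of gene length, of AN2-3 alone and of other groupings were written before theirs, but that of AN2-3 replaced an earlier one on the called genes.

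Several gene groups were not called as lists in any comparison with all 9 libraries. In mitochondrial respiration edgeR called 1 of 22 genes (NDA1, higher in AN2 than in AN0), where DESeq2 called 1 higher and 3 lower, and its camera adjusted p lay between 0.306 and 0.993 over the 3 comparisons. WRKY factors (8 genes, 0.460 to 0.756), cold, drought and heat response (11 genes, 0.740 to 0.902), ribosomal proteins (14 genes, 0.222 to 0.872), ascorbate and glutathione (10 genes, 0.740 to 0.872) and burst oxidases with calcium-dependent and MAP kinases (18 genes, 0.102 to 0.533) had 0 genes called by edgeR, at most 3 at an unadjusted p under 0.05 in any comparison, and at most 1 called by DESeq2. By edgeR, cell wall had STUGE51 as its only called gene of 13 (camera adjusted p from 0.624 to 0.740), and ion channels and pumps had PT1 as the only one of 10 (0.121 to 0.770). DESeq2 called 2 cell wall genes higher and 1 lower in AN2 against AN1 and 2 lower in AN2 against AN0, and 1 ion channel or pump gene higher in AN0 against AN1 and 1 higher and 1 lower in each of the other comparisons. Some of these lists were called by camera with a library left out: WRKY factors higher in AN0 without AN0-2 (camera adjusted p = 0.0423 against AN1 and 0.0395 against AN2), ribosomal proteins lower in AN2 than in AN1 without AN2-2 (0.00538), and burst oxidases and kinases lower in AN2 than in AN0 without AN2-3 (0.0185) and without AN0-1 and AN2-3 together (0.0126). The 4 genes for 14-3-3 proteins, 3 cytokinin oxidases and 3 D-type cyclins were too few for camera and had 0 genes called by edgeR, at most 2 at an unadjusted p under 0.05 in any comparison, and 1 called by DESeq2, a D-type cyclin in AN2 against AN0. Adjusted over the list alone, 1 D-type cyclin was lower in AN0 than in AN1 and 1 higher in AN2 than in AN0. In AN2 against AN1, 1 cytokinin oxidase was higher and 1 lower by the same measure, and in AN0 against AN1 1 was higher. Median and mean log2 fold change differed in sign for sucrose metabolism in AN2 against AN1 (-0.02 and 0.53), lipoxygenases there (-0.15 and 0.10), WRKY factors there (-0.16 and 0.07), cold, drought and heat response in AN0 against AN1 (-0.04 and 0.25), cell wall in AN0 against AN1 (-0.11 and 0.18) and in AN2 against AN0 (0.04 and -0.56), and ion channels in AN2 against AN0 (-0.23 and 0.26). They also did for mitochondrial respiration and cytokinin oxidases, the last not in AN2 against AN0. Camera pointed down against a positive median for glycoalkaloids (0.25) and ribosomal proteins (0.10) in AN2 against AN0, and for cell wall in the same comparison.

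Low storage transcripts and high photosynthesis transcripts met in AN0-1 and AN2-3. For sequencing depth, the highest library total was 1.24 times the lowest, while the patatin share of raw counts in AN0-1 lay 5.06-fold below the highest library. That share is already scaled by the library total, so the comparison could hardly have gone otherwise and adds little. Dilution of stolon RNA by green tissue may contribute but could not be settled. In AN2-3 the 6 storage genes differed from the other AN2 libraries by a median of -4.71 on the log2 scale and by a range of 7.86 between genes, from -7.27 for LOC102577642 to 0.59 for PIN-II (LOC102577839), and what the other tissue would itself express is unknown. The pattern crosses 2 treatments, so no biological explanation was tested, and a difference in stolon stage or light exposure stays open as untested.

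Nitrate and nitrite reductase were highest in the libraries labelled AN0, the nitrogen-poor treatment, although nitrate is the usual inducer of both genes. For green tissue in the AN0 libraries, the AN2 against AN0 change with the photosynthesis score as a covariate was -4.68 ± 0.60 for NR3 and -3.80 ± 0.65 for NIR. That score overlapped widely between the groups (-3.44 to 5.45 in AN0, -1.45 to 4.17 in AN2). The covariate could therefore hardly have removed the change, and the test decides little. AN0 against AN1 was not refitted in this way. AN0-3, with the lowest score of all, still lay above every AN1 and AN2 library for both genes, but it is 1 library. For single libraries exchanged between AN0 and AN2, the lowest AN0 library had 9.48 times the NR3 level of the highest AN2 library, and 4.08 times for NIR. This argues against such an exchange only if both genes follow the treatment. The pattern was also read from these same values, so the test is weak. Whole groups AN0 and AN2 exchanged cannot be told apart from correct labels here, because the 23.3-fold ratio of the NR3 means would arise either way. No gene that marks the treatment independently was identified, and most genes are known by number only. The nitrogen treatment itself stays open, for example through a different nitrogen form or sink state in these stolons, which was not tested.

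More genes were called higher than lower in AN2 against AN1 (92.6% of 148). For scaling between libraries, the share was at least 92.1% with RLE factors, upper-quartile factors and FPKM, which is scaled by library totals alone, although DESeq2's larger set had 75.3%. All 148 calls were at least 2-fold, so a modest change of scale could hardly turn their direction. FPKM leaves out the TMM factors (1.18, 0.920 and 1.21 in AN2-1 to AN2-3, 0.947 to 0.983 in AN1), which raises AN2-1 and AN2-3 against AN1. The share thus did not hinge on the choice among these factors, but scaling as a cause was not settled. Called genes were shorter than tested genes (median 1161 against 1647 bases), and a gene length correction shifted log2 fold changes by a median of 0.07, called 220 genes and left 108 of the 148 called, with a share of 85.9%, which argues against length as the whole cause. AN2-3 alone could not be settled. Without it the count of calls fell to 1, but it fell as far without AN1-1 (0), AN1-2 (1), AN1-3 (0) or AN2-1 (0), so that fall is not particular to AN2-3. Of the 2264 genes at an unadjusted p under 0.05 without AN2-3, 61.5% were higher, beside 69.4% of 2930 with it. The median log2 fold change of the genes called higher (2.14 without it, 2.29 with it) decides nothing, since those genes were chosen with AN2-3 in the fit. A response to excess nitrogen stays open as well, as untested.

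Other groupings of the libraries were refitted in the same way. Of 100 splits of the 9 libraries into 3 groups of 3, drawn from all such splits, only 1, the real one, reached 595 called genes, and the highest other gave 274. Random regrouping of these libraries thus rarely gives that count. It cannot separate the treatment from plants, pots or plots that the libraries of a treatment may share. The 10 splits of 6 libraries are too few for a share under the threshold. In these 2-group fits AN2 against AN0 called 119 genes with 0 in the highest other split, AN2 against AN1 45 with 0, and AN0 against AN1 0 with 0 in the others. Lists behaved differently: the real splits called 7, 0 and 4 lists for AN0 against AN1, AN2 against AN1 and AN2 against AN0, and the highest other splits 9, 7 and 8. Counts as large as the real one came in 3, 10 and 4 of the 10 splits for lists, and in 10, 1 and 1 for genes.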
